A study of Mus musculus with 3 samples.

How the data were processed

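Knee synovium of arthritic mice was dissociated with collagenase and DNase, and single cells were captured in droplets with the DNBelab C kit and sequenced on a DNBSEQ-T7 instrument, per the labels. The deposited matrices hold UMI counts per gene and barcode, written by PISA 1.0 per the file headers. The submitters' notes name Seurat 3.0.2 in R 3.6 and the genome build GRCm39 (mm39). The aligner and the gene annotation are not given in the sources used here. Gene names were taken as the matrices give them. Genomic spans were looked up by symbol in a reference annotation of the earlier mouse build, so no coordinates are given.

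The labels state 11111, 10668 and 14363 cells for replicates 1, 2 and 3, while the matrices held 11939, 11602 and 15263 barcodes. The stated mean UMI counts of 5432.73, 5392.78 and 5291.42 and median gene counts of 1506, 1406.5 and 1712 were also below the measured means of 8492, 8600.5 and 7608 UMIs and medians of 1745, 1653 and 1907 genes. No simple filter that was tried gave the stated values, and all barcodes were the starting point here. The lowest barcode held 1000 UMIs. Of 24357 gene symbols, 21479 were in all 3 matrices and 2878 in some only, where the others were taken as 0.

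Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept, which left out 82. Doublets, droplets with more than 1 cell, were scored per library with Scrublet as implemented in scanpy 1.11.5 at an expected rate of 6%. The automatic threshold marked only 2 cells (0.0173%) in replicate 2, so a score of 0.2 was used in every library, chosen after the scores were seen. This left out 479, 479 and 895 cells, 4.02%, 4.14% and 5.87%, or 1853 in all, and 36869 cells were analysed.

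Cells were normalised to a sum of 10000, log-transformed and scaled with a limit of 10. Cells were then clustered by the Leiden method (leidenalg 0.10.2, igraph 0.11.9) on 30 principal components of 2000 variable genes with 30 neighbours, seed 1 and resolution 1.0, and sub-clustered at 0.5. The 239 genes of the 17 fixed lists were left out of the variable genes. Clusters were named from fixed marker lists. A marker counted when at least 10% of a cluster's cells held it at 2 or more times the median CPM of the other clusters. A name needed 3 such markers that made up at least 75% of its list, or 3 of which at least 1 was among the 10 genes leading the cluster at 50 CPM or more. Sub-classes of fibroblasts and phagocytes needed 3 that were over 50% of their list. A sub-cluster without another class's name and with 3 or more proliferation-list genes among its 10 leading genes was called cycling. A sub-cluster that met no rule kept its parent's name if 3 or more parent markers were each seen in 10% of its cells. No fold was required for this. A cluster whose median depth was under 0.333 of its library's and that none of its markers led stayed unnamed. Names carry the ending "-like", since they rest on RNA alone. Sub-clusters with the markers of another class, mixed profiles, were left out of the comparisons. Gamma-delta T cells were not named here. The level of 1 gene in the T cell-like sub-clusters is not reported here.

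UMI counts were summed per library and class, with at least 20 cells per sum. Each comparison set 2 classes against each other in the 3 libraries with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F-test, two-sided) and the library as a block, since both sums of a library came from the same mice. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The p-values measure the spread between 3 libraries, each of 2 pooled mice, and not between single mice. Levels in CPM are of all UMIs of a class, while fold changes follow TMM scaling, so the ratio of levels can differ from the fold change. Classes were made from the same UMIs that were tested, and markers of a class are not reported as results of a comparison.

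Fixed lists covered inflammatory cytokines, neutrophil-attracting chemokines, monocyte- and lymphocyte-attracting chemokines, chemoattractant receptors, cytokine receptors, matrix-degrading proteases and their inhibitors, extracellular matrix, Fc receptors and immune-complex signalling, complement components, MHC class II presentation and co-stimulation, interferon-stimulated genes, eicosanoid synthesis, LPS sensing and NF-kB response, bone and cartilage remodelling signals, glycolysis and hypoxia, proliferation, and dissociation response. Named genes were, from each list, the called gene with the largest absolute log2 fold change in each direction, with that direction in all libraries and at least 10 CPM in the higher class. Il1b, Tnf, Il6, Osm, Cxcl1, Cxcl2, Ccl2, Mmp3, Mmp13 and Tnfsf11 were named in every comparison whatever the test gave. Acod1 and Cnmd were found under the older symbols Irg1 and Lect1. The comparisons, lists, markers, named-gene rule and most alternatives were fixed before the data were examined.

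Free RNA, released by broken cells into all droplets, was bounded per class and library by the UMIs of the 2 neutrophil genes S100a8 and S100a9 in cells other than neutrophils, as a share of the profile of the library. The resulting free RNA limit of a gene is its level in that profile times this share. It assumes that free RNA has the make-up of the whole library, and a gene that free RNA holds more of can exceed it. It was not computed for neutrophil-like cells, from which nothing was subtracted. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals.

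Alternatives were DESeq2 size factors, library totals alone, the DESeq2 1.42.0 Wald test, no filter on low counts, no replicate block, leaving out each replicate, at least 500 genes and at most 10% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2.0, clustering and testing on separate random parts of the UMIs, and cells thinned to 1000 UMIs with equal cell numbers. Added after the data were seen were tenocyte-like cells pooled with sublining-fibroblast-like cells, immature-neutrophil-like cells pooled with neutrophil-like cells, only the infiltrating-monocyte-like sub-cluster led by its markers, mixed profiles kept, and free RNA subtracted. The test was tested on simulated data with 100 genes changed 4-fold and 100 changed 8-fold. It recovered 100% and 100% in the fibroblast-like comparison, 99% and 100% in the neutrophil-like, 100% and 100% in the lining-fibroblast-like and 90% and 97% in the resident-macrophage-like comparison. The simulated changes were few among all genes, as many up as down, and without differences between libraries. The simulation therefore did not test the scaling where many genes differ, nor changes smaller than 4-fold. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.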

Results

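Single-cell gene expression was measured in the inflamed knee synovium of female C57BL/6 mice with collagen and antibody-induced arthritis. In this model, mice are immunised with type II collagen and later given antibodies against collagen followed by lipopolysaccharide (LPS), which together bring on a destructive joint inflammation. The mice were 8 weeks old, were immunised on day 0 with 100 µg of collagen, received 1 mg of antibodies on day 21 and LPS on day 22, and were sampled at the effector phase. The 3 libraries, replicates 1 to 3, formed 1 group, and each held the pooled synovium of 2 mice, so 6 mice in all. There was no untreated group, so no value could be set against healthy synovium.

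Replicate 1 held 101384374 UMIs (unique transcript molecules) over 11939 barcodes, replicate 2 held 99782608 over 11602 and replicate 3 held 116125707 over 15263. The median barcode carried 4909, 4702 and 5267 UMIs and 1745, 1653 and 1907 genes, respectively, and a median mitochondrial share of 0.700%, 0.575% and 0.652%. After low-quality barcodes and doublets were left out, 36869 cells remained. Intervals and limits given for shares cover counting error only. Expression levels are given as UMIs in 1000000 UMIs of a class (CPM), as the mean ± SD of the 3 libraries.

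Neutrophil-like cells, the short-lived granulocytes of acute inflammation, made up 30.5% ± 5.57 of cells (SD, n = 3 libraries), and monocyte/macrophage-like cells made up 30.1% ± 5.01. The neutrophil-like share was 20.8% with doublets kept and 23.2% at resolution 2.0, both clustered anew. The median neutrophil-like cell held 1871, 1984 and 1548 UMIs in replicates 1, 2 and 3. No barcode held under 1000 UMIs, so neutrophils below that floor are not in the share. Fibroblast-like cells, the stromal cells that build and degrade the synovial matrix, made up 15.9% ± 4.17, not counting tenocyte-like cells. Among the phagocytes, infiltrating-monocyte-like cells formed 14.4% ± 1.52 of all cells and resident-macrophage-like cells, the long-lived macrophages of the healthy membrane, 0.618% ± 0.0356. Among the stroma, lining-fibroblast-like cells formed 5.31% ± 1.08, sublining-fibroblast-like cells 3.12% ± 0.969 and tenocyte-like cells 6.05% ± 0.622, which dropped to 2.39% when clustered anew at resolution 2.0. The tenocyte-like name rests on 3 markers. These cells also met the rule for the sublining-fibroblast-like name and took the name with the higher marker score, so the 2 shares depend on that choice. Cycling cells were found in both compartments, with 4.40% ± 1.18 of cells in the phagocytes and 2.75% ± 0.732 in the fibroblasts. Endothelial-like cells formed 3.11% ± 0.739, T cell-like cells 2.31% ± 0.206 (1.503% when clustered anew at resolution 0.5), pericyte/smooth-muscle-like cells 1.86% ± 0.153, dendritic-cell-like cells 1.04% ± 0.188 and osteoclast-like cells, the bone-resorbing cells, 0.904% ± 0.218. B cell-like cells were scarce, at 0.228% ± 0.0415. Immature-neutrophil-like cells formed 1.30% of replicate 1 (exact 95% binomial interval 1.10 to 1.53), 4.28% of replicate 2 (3.91 to 4.67) and 0.523% of replicate 3 (0.411 to 0.655), an 8.18-fold spread. Granulocyte/monocyte-progenitor-like cells showed a 12.6-fold spread, from 0.132% in replicate 3 to 1.67% in replicate 2.

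**Figure D1:**
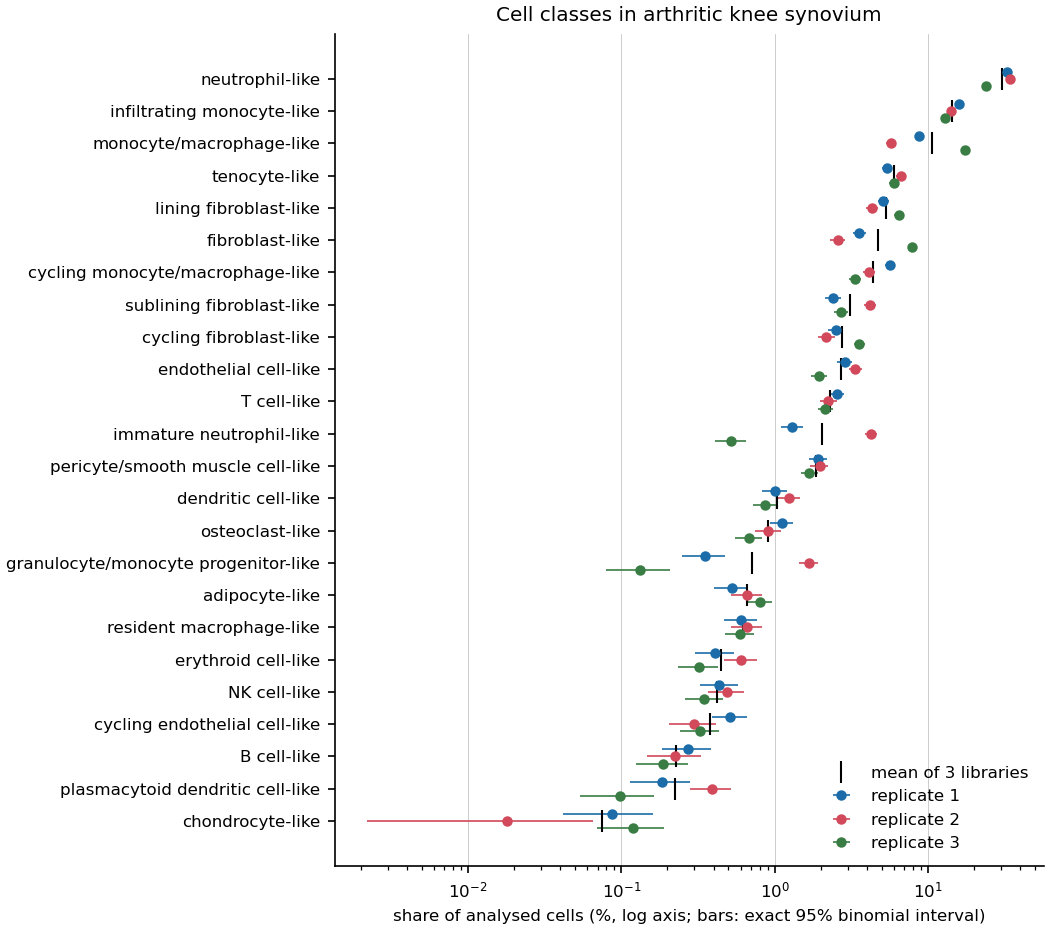
Share of analysed cells (%, log axis) by cell class, with 1 point per library, its exact 95% binomial interval and a black line at the mean of the 3 libraries. Neutrophil-like cells averaged 30.5%, with 33.1%, 34.3% and 24.1% in replicates 1, 2 and 3, and the 3 libraries lay farthest apart, among classes over 0.5%, in granulocyte/monocyte-progenitor-like cells.

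The mediators of joint inflammation fixed in advance fell into different classes among the 21 with at least 20 cells in every library. Il1b, which encodes a central pyrogenic cytokine, reached 5926 ± 274 CPM in neutrophil-like cells (SD, n = 3) and 730.4 ± 63.7 in infiltrating-monocyte-like cells. Dendritic-cell-like cells held 734 ± 137 CPM of Il1b, against a free RNA limit of 164 CPM, the level that RNA released by broken cells would give there if it had the make-up of the whole library and brought all S100a8 and S100a9 UMIs of the class. Tnf, the target of anti-TNF drugs, was found at 299 ± 42.9 CPM in neutrophil-like, 145 ± 21.2 in T cell-like and 106 ± 9.40 in infiltrating-monocyte-like cells. Il6 was highest in lining-fibroblast-like cells, at 51.7 ± 22.9 CPM with a free RNA limit of 2.15. The collagenase gene Mmp13 and the stromelysin gene Mmp3 were highest in fibroblast-like cells outside the lining, sublining and cycling sub-classes, at 260.0 ± 19.5 and 3238 ± 799 CPM. Sublining-fibroblast-like cells came close in Mmp13, at 246 ± 34.5 CPM, and were higher in replicate 3 (284 against 259). The cells outside these sub-classes also held the lining marker Prg4 at 13282 ± 3374 CPM. Lining-fibroblast-like cells held 20469.5 ± 3968 and sublining-fibroblast-like cells 4283 ± 539, so the missing name does not place those cells outside the lining layer. The 29 chondrocyte-like cells, too few to be among the 21 classes, held Mmp13 at 305, 283 and 1407 CPM in replicates 1, 2 and 3. These levels come from 10, 2 and 17 cells. The replicate 2 value rests on 11 UMIs of 2 cells, which held 0 UMIs of the chondrocyte marker Col2a1. This sub-cluster also met the rule for an osteoblast name. Tnfsf11, which encodes the osteoclast-inducing ligand RANKL, reached 144 ± 46.8 CPM in T cell-like cells and 41.4 ± 9.26 in sublining-fibroblast-like cells. Its receptor gene Tnfrsf11a reached 113 ± 8.92 CPM in osteoclast-like and 94.3 ± 7.70 in cycling monocyte/macrophage-like cells. Il17a, a T-cell cytokine that acts on stroma, stood at 83.4 ± 51.5 CPM in T cell-like cells, with 47.0, 60.9 and 142 in replicates 1, 2 and 3. Il1b in fibroblast-like cells, at 177 ± 10.6 CPM, was 1.33 times the free RNA limit of 133 CPM.

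**Figure D2:**
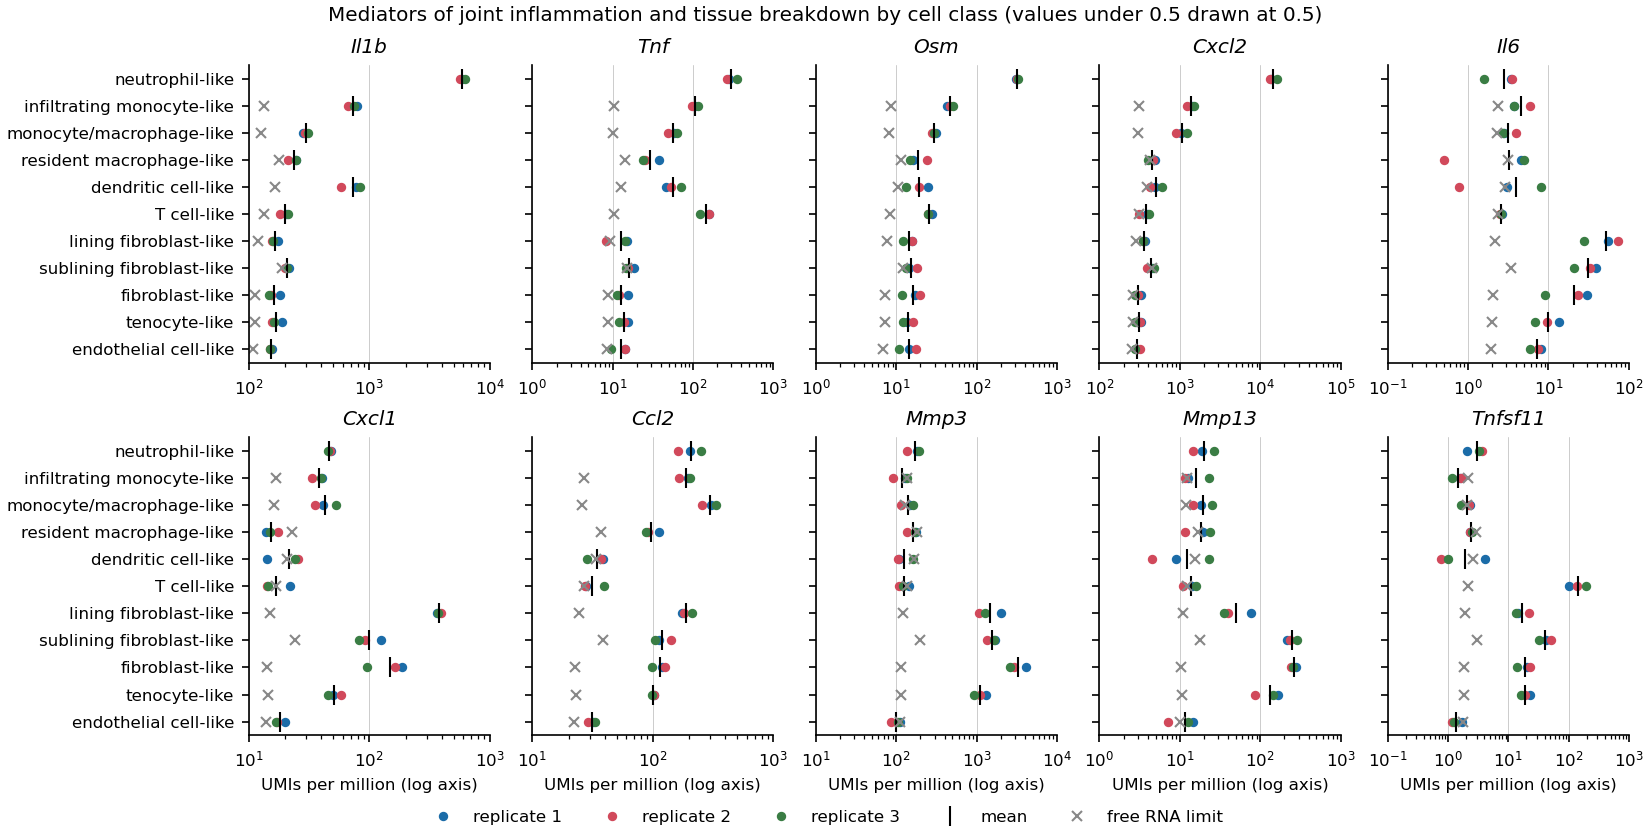
Levels of 10 mediators in 11 classes in CPM (log axes, values under 0.5 drawn at 0.5), with 1 point per library, a line at the mean and a cross at the free RNA limit, which was not computed for neutrophil-like cells. Il1b, Tnf, Osm and Cxcl2 were highest in neutrophil-like cells, and Il6, Cxcl1, Mmp3 and Mmp13 in fibroblast-like classes.

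Fibroblast-like cells were compared with monocyte/macrophage-like cells to see which compartment of the same joints carried which inflammatory and tissue-breakdown genes. The fibroblast-like class here joined the lining, sublining, cycling and other fibroblast-like cells, and the 2226 tenocyte-like cells were left out. The fibroblast-like cells held more Il6, at 37.0 ± 15.1 CPM against 3.75 ± 0.898 (SD, n = 3 libraries), and more of the matrix protease gene Mmp3, at 1869.8 ± 467 against 131 ± 25.9. They also held more Mmp13, at 138 ± 3.23 against 17.1 ± 6.05, and more Tnfsf11, at 22.7 ± 7.34 against 1.77 ± 0.249. The monocyte/macrophage-like cells held more Tnf, at 71.9 ± 3.90 CPM against 13.6 ± 2.30, and more Il1b, at 472 ± 31.2 against 177 ± 10.6. By edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, 6377 of 15148 genes were called, 3504 higher and 2873 lower in fibroblast-like cells, and 6370 of the called genes had their direction in all 3 libraries.

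Log2 fold changes ± SE are of fibroblast-like over monocyte/macrophage-like cells. Of 17 tested inflammatory cytokine genes, 7 were higher, 6 lower and 4 not called, among them Il6 (3.26 ± 0.15) and Tnf (-2.39 ± 0.09), Il1b (-1.39 ± 0.07) and Osm (-1.18 ± 0.09). Among 6 neutrophil-attracting chemokine genes, 3 were higher and 2 lower, with Cxcl5 (4.01 ± 0.11) and Cxcl1 (2.61 ± 0.10) on the fibroblast side and Cxcl2 (-1.55 ± 0.09) on the phagocyte side. The 18 monocyte- and lymphocyte-attracting chemokine genes split into 5 higher, such as Cxcl12 (3.37 ± 0.09), a homing signal for leukocytes, 7 lower, such as Ccl8 (-4.07 ± 0.16), and 6 not called. Ccl2, which recruits monocytes, was not called, at -0.30 ± 0.11. Chemoattractant receptors were lower for 8 of 10 genes, led by the complement C3a receptor gene C3ar1 (-3.99 ± 0.12). Of 17 cytokine receptor genes, 4 were higher, including Il17rc (4.16 ± 0.11), part of the IL-17 receptor, and 7 lower, including Csf2rb (-3.48 ± 0.08). The bone and cartilage remodelling signals were higher for 11 of 14 genes, such as Tnfsf11 (3.65 ± 0.13), and lower for 1, its receptor Tnfrsf11a (-4.40 ± 0.12).

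Of 18 matrix-degrading protease and inhibitor genes, 9 were higher and 5 lower, with the aggrecanase gene Adamts5 (4.53 ± 0.09) and the collagenase gene Mmp13 (3.07 ± 0.14) higher and the cathepsin gene Ctss (-4.23 ± 0.11) lower. Extracellular matrix genes were higher for 16 of 17, led by Sparc (4.14 ± 0.12). Complement genes were split, with 7 of 13 higher, such as Cd55 (3.48 ± 0.10), a regulator of complement, and 4 lower, such as C1qa (-4.35 ± 0.12), which starts the classical pathway. Of 9 Fc receptor and immune-complex genes, 8 were lower, such as the high-affinity IgG receptor gene Fcgr1 (-4.30 ± 0.10), and 1, the IgG-recycling receptor gene Fcgrt (1.87 ± 0.11), was higher. All 10 MHC class II and co-stimulation genes were lower, led by Cd86 (-4.46 ± 0.11). Interferon-stimulated genes were lower for 7 of 15, such as Ifi27l2a (-3.48 ± 0.09). Of 10 eicosanoid genes, 3 were higher, such as Ptgs1 (2.67 ± 0.16), a prostaglandin synthase, and 4 lower, such as Hpgds (-4.26 ± 0.16). The LPS and NF-kB response list had 11 of 17 genes lower, including the LPS co-receptor gene Cd14 (-2.48 ± 0.10), and 3 higher, including Lcn2 (2.93 ± 0.23). Glycolysis and hypoxia genes were lower for 3 of 16, such as Pfkfb3 (-1.49 ± 0.08), proliferation genes higher for 10 of 12, such as Ube2c (2.39 ± 0.15), and dissociation-response genes, which tissue digestion induces, lower for 6 of 12, such as Atf3 (-2.10 ± 0.08). How much digestion moved the LPS and NF-kB response list and the other lists was not tested. The nuclear RNA Malat1 was lower as well, at -1.73 ± 0.17.

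With edgeR and Benjamini-Hochberg adjustment over all genes, the adjusted p of the 27 genes named from the lists ran from 3.09e-10 to 1.06e-06. Each had its direction in 3 of 3 libraries. The naming rule took only called genes with the same direction in all libraries, so neither is separate support. Counts adjusted over the list alone differed in 0 of the 17 lists. On the assumption that it has the make-up of the whole library, free RNA could account for at most 16.8%, 14.2% and 20.6% of the UMIs of fibroblast-like cells in replicates 1, 2 and 3, and for 15.9%, 14.8% and 20.7% in monocyte/macrophage-like cells. With every cell thinned to 1000 UMIs and classes made equal in cell number, 3850 genes were called, and with free RNA subtracted Cxcl2 (-4.74) and Cd14 (-5.35) were not called. Their fold changes were larger in size than without subtraction, and the calls ended on the edgeR adjusted p (Benjamini-Hochberg) of 0.178 and 0.102.

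**Figure D3:**
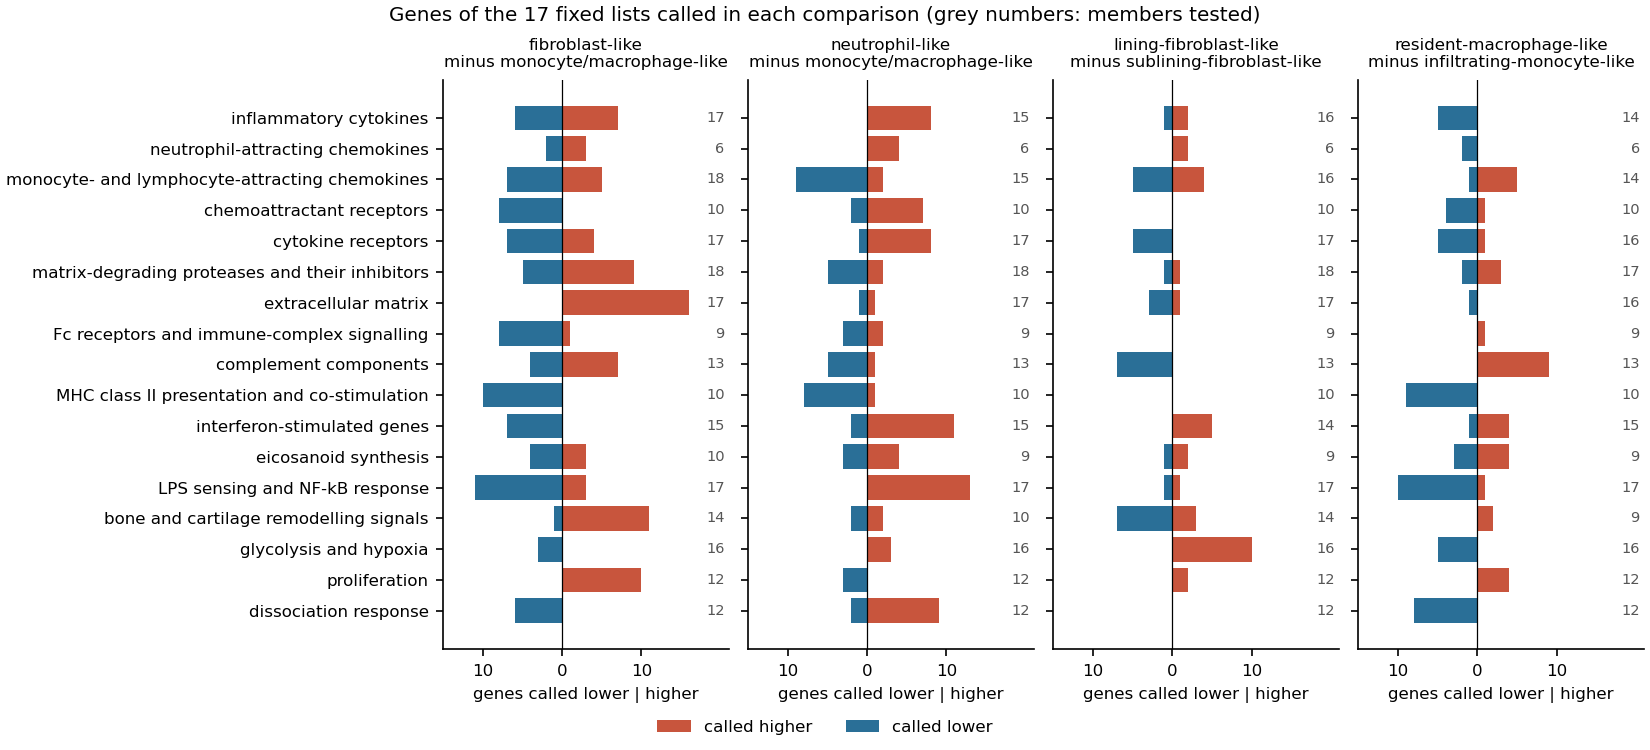
Number of genes of each fixed list called higher (right) and lower (left) in the first class of each of the 4 comparisons, with the number of tested members in grey. All 10 MHC class II and co-stimulation genes were lower in fibroblast-like cells, and 13 of 17 LPS and NF-kB response genes were higher in neutrophil-like cells.

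Neutrophil-like and monocyte/macrophage-like cells were compared as the main leukocytes of the inflamed membrane. Neutrophil-like cells held more Il1b, at 5926 ± 274 CPM against 472 ± 31.2 (SD, n = 3 libraries), and more of the neutrophil attractant Cxcl2, at 14308 ± 1500.4 against 1086 ± 128. Tnf stood at 299 ± 42.9 against 71.9 ± 3.90 CPM, and Osm, a cytokine that acts on stromal cells, at 319 ± 6.44 against 34.8 ± 0.526. The macrophage growth factor gene Csf1 was higher in neutrophil-like cells as well, at 402 ± 84.9 against 17.8 ± 1.74 CPM. Of 13877 genes tested with edgeR quasi-likelihood and Benjamini-Hochberg adjustment, 6596 were called, 3120 higher and 3476 lower in neutrophil-like cells, and 6567 of these had their direction in all 3 libraries.

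The log2 fold changes ± SE here are of neutrophil-like over monocyte/macrophage-like cells. Inflammatory cytokine genes were higher for 8 of 15 tested and not called for 7, with Csf1 (4.85 ± 0.09), Il1b (4.02 ± 0.10), Osm (3.57 ± 0.09) and Tnf (2.42 ± 0.08) among the former and Il6 (0.01 ± 0.23) among the latter. Neutrophil-attracting chemokine genes were higher for 4 of 6, such as Ccl4 (4.41 ± 0.10) and Cxcl2 (4.09 ± 0.11), while Cxcl1 (0.67 ± 0.10) was not called. Monocyte- and lymphocyte-attracting chemokine genes were mostly lower, 9 of 15, such as Ccl12 (-3.65 ± 0.16), with 2 higher, such as Ccl6 (1.59 ± 0.12). Ccl2 was not called, at 0.34 ± 0.08. Chemoattractant receptor genes were higher for 7 of 10, led by Cxcr2 (6.39 ± 0.10), the receptor for the CXC chemokines above, and lower for 2, such as C3ar1 (-3.29 ± 0.10). Of 17 cytokine receptor genes, 8 were higher, led by the IL-1 decoy receptor gene Il1r2 (5.34 ± 0.10), and 1, Lifr (-1.45 ± 0.17), was lower. The LPS and NF-kB response list was higher for 13 of 17 genes, led by Lcn2 (4.63 ± 0.11), an iron-sequestering antimicrobial protein. Interferon-stimulated genes were higher for 11 of 15, such as the antiviral gene Rsad2 (4.54 ± 0.09), and lower for 2, such as Bst2 (-1.89 ± 0.09).

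Of 18 protease and inhibitor genes, 2 were higher, led by the gelatinase gene Mmp9 (5.04 ± 0.10), 5 lower, such as the macrophage elastase gene Mmp12 (-2.98 ± 0.17), and 11 not called, with Mmp3 (0.75 ± 0.08) and Mmp13 (0.61 ± 0.10) among them. Extracellular matrix genes gave 1 higher, Cd44 (2.04 ± 0.09), 1 lower, Fn1 (-1.21 ± 0.08), and 15 not called. Fc receptor and immune-complex genes gave 2 of 9 higher, such as the kinase gene Syk (2.50 ± 0.08), and 3 lower, such as Fcgr1 (-3.12 ± 0.10). Complement genes were lower for 5 of 13, such as C1qa (-3.78 ± 0.09), and higher for 1, and MHC class II and co-stimulation genes lower for 8 of 10, such as H2-DMb1 (-3.49 ± 0.10), and 8.01-fold higher for 1, the co-stimulatory gene Cd80. Of 9 eicosanoid genes, 4 were higher, including the leukotriene-forming enzyme gene Alox5 (4.36 ± 0.10), and 3 lower, including Hpgds (-3.09 ± 0.19). The bone and cartilage list gave 2 of 10 higher, Tnfsf11 (1.12 ± 0.26) and Nfatc1 (1.04 ± 0.08), and 2 lower, including Tnfrsf11a (-3.41 ± 0.11). Tnfsf11 was low in both classes, at 3.02 ± 0.839 and 1.77 ± 0.249 CPM. Glycolysis and hypoxia genes were higher for 3 of 16, such as the lactate exporter gene Slc16a3 (2.21 ± 0.10), and proliferation genes lower for 3 of 12, such as Mcm5 (-1.61 ± 0.16). Dissociation-response genes were higher for 9 of 12, such as Dusp1 (3.17 ± 0.09), and lower for 2, such as Hspa8 (-1.59 ± 0.08). Whether digestion also moved the cytokine, chemokine and LPS and NF-kB response genes of this comparison was not tested. Malat1 and Neat1 were higher, at 1.10 ± 0.09 and 2.73 ± 0.08. Genes called higher went from 20.8% in the shortest of 4 equal groups of tested genes by genomic span to 30.2% in the longest, and genes called lower from 31.1% to 18.0%.

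Adjusted p (edgeR quasi-likelihood, Benjamini-Hochberg) of the 28 genes named from the lists ran from 3.93e-30 to 3.31e-09. All had their direction in 3 of 3 libraries, which the naming rule required, as it did the call. Counts adjusted over the list alone differed in 0 of the 17 lists. Scaled by library totals alone, which lowered the median log2 fold change of all genes by 0.37, 6949 genes were called, 2205 higher and 4744 lower, and 15 of 124 listed genes called with TMM scaling were no longer called. With free RNA subtracted from the monocyte/macrophage-like cells alone, 7068 genes were called, 3839 higher and 3229 lower. The median neutrophil-like cell held 1871, 1984 and 1548 UMIs in replicates 1, 2 and 3, while in the classes that make up the monocyte/macrophage-like cells the median was 6606.5, 5965 and 4948.5 in infiltrating-monocyte-like, 8627, 7277 and 6569 in cycling, 11296, 10690 and 7487 in resident-macrophage-like and 7852, 8017 and 5863 in the other cells. Nfatc1 was not called without replicate 1 (0.97) or replicate 3 (0.94), nor was Tnfsf11 without replicate 2 (0.89) or replicate 3 (0.90), and library totals alone ended both calls (0.66 and 0.74), as thinning did for Mcm5 (-0.78).

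Lining-fibroblast-like and sublining-fibroblast-like cells were named by markers of the surface layer that faces the joint cavity and of the vascular tissue beneath it. The sublining-fibroblast-like name rests on 4 of its markers, and 0 of them were among the 10 genes leading that sub-cluster, which include Naaladl2, Meg3 and Mid1, so the name is less firm than that of the lining-fibroblast-like cells, which 2 of their markers led. The lining-fibroblast-like cells held more of the neutrophil attractant Cxcl1, at 376 ± 15.4 CPM against 99.7 ± 22.0 (SD, n = 3 libraries), and more of the nitric oxide synthase gene Nos2, at 99.3 ± 23.7 against 21.1 ± 7.25. The sublining-fibroblast-like cells held more of the central complement gene C3, at 2683 ± 162 against 359 ± 38.7, more Mmp13, at 246 ± 34.5 against 50.7 ± 22.3, and more Tnfsf11, at 41.4 ± 9.26 against 16.7 ± 4.65. Clustered anew at resolution 2.0, the direction turned for Mmp13, to a log2 fold change of 0.64, not called, and for Tnfsf11, to 1.31, called higher in lining-fibroblast-like cells. The hyaluronan synthase genes parted, with Has1 higher in the lining-fibroblast-like cells, 282 ± 123 against 51.0 ± 24.6 CPM, and Has2 in the sublining-fibroblast-like cells, 60.4 ± 28.6 against 6.41 ± 1.66. Of 12826 genes tested with edgeR quasi-likelihood and Benjamini-Hochberg adjustment, 2834 were called, 737 higher and 2097 lower in lining-fibroblast-like cells, 2821 of them with their direction in all 3 libraries.

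Log2 fold changes ± SE in this comparison are of lining- over sublining-fibroblast-like cells. Of 16 inflammatory cytokine genes, 2 were higher, led by Il11 (3.01 ± 0.21), 1 was lower, Il1rn (-1.15 ± 0.14), and 13 were not called, among them Il6 (0.87 ± 0.13), Il1b (-0.19 ± 0.08), Tnf (-0.24 ± 0.17) and Osm (0.08 ± 0.13). Il6 was called without replicate 1, at 1.02, and Il1rn was not called without replicate 2, at -0.91. Neutrophil-attracting chemokine genes were higher for 2 of 6, Cxcl3 (3.48 ± 0.27) and Cxcl1 (2.09 ± 0.13), while Cxcl2 (-0.13 ± 0.08) was not called. Of 16 monocyte- and lymphocyte-attracting chemokine genes, 4 were higher, such as Ccl5 (2.55 ± 0.14), and 5 lower, such as the B-cell attractant Cxcl13 (-3.64 ± 0.15). Ccl2 stood at 0.83 ± 0.12 and was called without replicate 2, at 1.03. Cytokine receptor genes were lower for 5 of 17, including the IL-1 receptor gene Il1r1 (-2.06 ± 0.11), and complement genes lower for 7 of 13, led by C3 (-2.75 ± 0.10). Glycolysis and hypoxia genes were higher for 10 of 16, led by Slc16a3 (1.86 ± 0.11), and interferon-stimulated genes higher for 5 of 14, such as Bst2 (1.46 ± 0.09). Fold changes in this comparison followed the genomic span of genes, as given below, and no list count was adjusted for it. The bone and cartilage list gave 3 of 14 higher, led by Bmp2 (2.40 ± 0.24), and 7 lower, among them Dkk2 (-3.80 ± 0.29), a Wnt regulator, and Tnfsf11 (-1.16 ± 0.12).

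Of 18 protease and inhibitor genes, 1 was higher, Timp1 (1.67 ± 0.10), an inhibitor of matrix metalloproteinases, 1 lower, Mmp13 (-2.19 ± 0.19), and 16 not called, including Mmp3 (0.01 ± 0.11). Extracellular matrix genes gave 1 of 17 higher, Has1 (2.64 ± 0.32), and 3 lower, led by Has2 (-3.04 ± 0.14). Eicosanoid genes gave 2 of 9 higher, led by Ptgs1 (2.55 ± 0.13), and 1 lower, the prostaglandin-degrading enzyme gene Hpgd (-4.65 ± 0.18). The LPS and NF-kB response list gave 1 of 17 higher, Nos2 (2.43 ± 0.10), and 1 lower, Nfkb1 (-1.15 ± 0.09), and proliferation genes were higher for 2 of 12, led by Rrm2 (1.20 ± 0.17), in classes from which cycling fibroblast-like cells had been kept apart by the naming. With edgeR, 0 of 10 chemoattractant receptor, 0 of 9 Fc receptor and immune-complex, 0 of 10 MHC class II and co-stimulation and 0 of 12 dissociation-response genes were called, and DESeq2 called 0 in each of these lists. At an unadjusted p under 0.05, the edgeR counts in these lists were 3, 2, 2 and 7. At a Benjamini-Hochberg adjusted p under 0.05 they were 1, 2, 0 and 6. Those genes missed the call on the fold limit alone, since absolute log2 fold changes in these lists were at most 0.79.

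Genes lower in the lining-fibroblast-like cells were long, since of 4 equal groups of tested genes by genomic span, 5.83% were called lower in the shortest group (median 5.42 kb) and 39.3% in the longest (median 111 kb). Genes called higher went from 11.4% to 2.63% over the same groups. The median log2 fold change of all tested genes was 0.44 in the shortest group and -0.73 in the longest. How much of the list results above goes with span was not tested. The nuclear RNAs Malat1 and Neat1, markers of nuclear RNA content, were lower in the lining-fibroblast-like cells, at -3.46 ± 0.10 and -2.13 ± 0.11, with Malat1 at 243 ± 35.5 against 2981 ± 394 CPM. On the same assumption as above, free RNA could account for at most 14.5%, 13.2% and 18.8% of lining-fibroblast-like and 27.7%, 15.9% and 30.2% of sublining-fibroblast-like UMIs in replicates 1, 2 and 3.

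**Figure D4:**
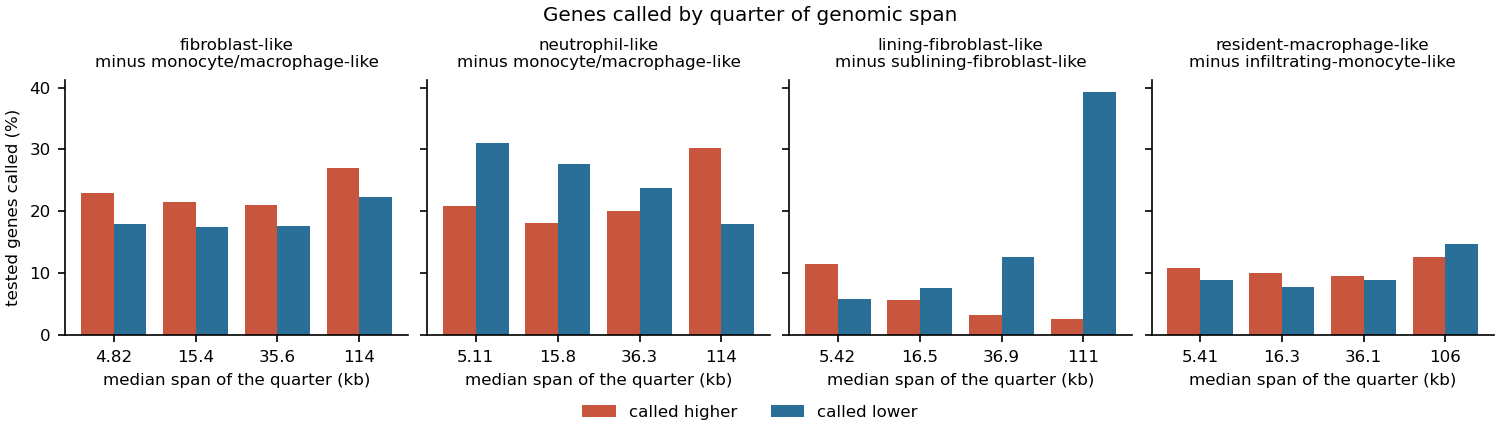
Percent of tested genes called higher and lower in the first class of each comparison, in 4 equal groups by genomic span, with the median span of each group in kb on the x axis. In lining- against sublining-fibroblast-like cells, genes called lower went from 5.83% in the shortest group to 39.3% in the longest.

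Adjusted p of the 20 genes named from the lists ran from 2.21e-10 to 3.77e-05 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. All had their direction in 3 of 3 libraries, and the naming rule required both this and the call. Counts adjusted over the list alone differed in 0 of the 17 lists. Scaled by library totals alone, the median log2 fold change of all genes dropped by 0.16, 512 genes were called higher and 2508 lower, and 7 of 64 listed genes called with TMM scaling were no longer called. Clustered anew at resolution 2.0, 1415 genes were called, Nfkb1 turned to 0.16 and Rrm2 to -0.033, Il6 rose to 4.14 and Mmp3 to 1.83, and Il1rn (-0.16), Il1r1 (-0.56) and Bst2 (0.52) were not called. Cells thinned to equal depth and number gave 1603 genes, and with tenocyte-like cells pooled into the sublining class Nfkb1 (-0.41) and Tnfsf11 (-0.70) were not called and Il6 (1.56) was. Rrm2 was not called with UMIs split (0.95), and Ccl2 was called with free RNA subtracted (1.12).

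Resident-macrophage-like cells were set against infiltrating-monocyte-like cells, classes named by markers of the macrophages already present in the membrane and of the cells that enter it in inflammation. Of the 3 sub-clusters named infiltrating-monocyte-like, only 1, of 1608 cells, had any of its markers among its 10 leading genes, and the other 2, of 1841 and 1813 cells, had 0, so that name is less firm than that of the resident-macrophage-like cells, which 2 of their markers led. The resident-macrophage-like cells held more of the monocyte attractant Ccl8, at 4647 ± 314 CPM against 16.2 ± 0.814 (SD, n = 3 libraries), and more C1qa, at 7614 ± 1062 against 552 ± 146. They held less Tnf, at 29.1 ± 7.69 against 106 ± 9.40, less Il1b, at 236 ± 20.3 against 730.4 ± 63.7, and less of the co-stimulatory gene Cd86, at 18.9 ± 4.42 against 219.6 ± 40.1. The Il1b of the resident-macrophage-like cells was 1.32 times the free RNA limit of 179 CPM there. Of 11662 genes tested by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 2429 were called, 1254 higher and 1175 lower in resident-macrophage-like cells, and 2393 of these had their direction in all 3 libraries.

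Resident-macrophage-like over infiltrating-monocyte-like cells gave the log2 fold changes ± SE that follow. Inflammatory cytokine genes were lower for 5 of 14, including Tnf (-1.78 ± 0.17), Il1b (-1.55 ± 0.12) and Osm (-1.24 ± 0.21), with Il6 (-0.41 ± 0.61) not called. Neutrophil-attracting chemokine genes were lower for 2 of 6, Cxcl2 (-1.53 ± 0.13) and Cxcl1 (-1.22 ± 0.22). Of 14 monocyte- and lymphocyte-attracting chemokine genes, 5 were higher, led by Ccl8 (8.24 ± 0.18), 1 lower, Cxcl10 (-2.18 ± 0.21), and 8 not called, including Ccl2 (-0.88 ± 0.13). Chemoattractant receptor genes gave 1 of 10 higher, C3ar1 (1.09 ± 0.11), and 4 lower, led by the leukotriene B4 receptor gene Ltb4r1 (-3.34 ± 0.21). Cytokine receptor genes gave 1 of 16 higher, Tgfbr2 (1.57 ± 0.14), and 5 lower, such as Csf2rb (-1.44 ± 0.13). Complement genes were higher for 9 of 13, led by C1qa (3.89 ± 0.15), and 1 of 9 Fc receptor and immune-complex genes was higher, Fcgrt (4.54 ± 0.13). MHC class II and co-stimulation genes were lower for 9 of 10, led by Cd86 (-3.43 ± 0.18). The LPS and NF-kB response list was lower for 10 of 17 genes, such as Nos2 (-2.16 ± 0.33), and higher for 1, the acute-phase gene Saa3 (1.24 ± 0.18). Clustered anew at resolutions 0.5 and 2.0, the direction of Nos2 turned, to 0.66 and 0.32, not called.

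Interferon-stimulated genes gave 4 of 15 higher, such as Ifi27l2a (2.22 ± 0.14), and 1 lower, Isg15 (-1.32 ± 0.14). Of 17 protease and inhibitor genes, 3 were higher, led by Timp2 (4.39 ± 0.14), 2 lower, such as Mmp8 (-1.81 ± 0.21), and 12 not called, with Mmp3 (0.53 ± 0.12) and Mmp13 (0.32 ± 0.25) among them. Eicosanoid genes gave 4 of 9 higher, led by the prostaglandin D synthase gene Hpgds (4.74 ± 0.18), and 3 lower, such as Ptgs2 (-1.55 ± 0.22), the inducible prostaglandin synthase. Extracellular matrix genes gave 1 of 16 lower, Cd44 (-1.13 ± 0.12), and bone and cartilage genes 2 of 9 higher, such as Sfrp2 (1.07 ± 0.33), a Wnt inhibitor, with Tnfsf11 (0.76 ± 0.70) not called. Sfrp2, the other gene, Bmp2, and Saa3 above were also called higher in fibroblast-like than in monocyte/macrophage-like cells. Free RNA richer in fibroblast RNA than the whole library was not tested for them. Glycolysis and hypoxia genes were lower for 5 of 16, such as the glucose transporter gene Slc2a1 (-1.83 ± 0.18), proliferation genes higher for 4 of 12, such as Mcm5 (1.75 ± 0.28), and dissociation-response genes lower for 8 of 12, such as Atf3 (-2.19 ± 0.16). Part of the cytokine and LPS and NF-kB response results may go with digestion, which was not tested. Cycling monocyte/macrophage-like cells were a class of their own, so the naming itself kept cells rich in proliferation genes out of both classes compared. Malat1 was lower too, at -1.05 ± 0.13. Adjusted over the list alone, protease genes gave 4 higher, interferon-stimulated genes 5 higher, eicosanoid genes 4 lower and dissociation-response genes 9 lower, and the counts of the other lists were the same.

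For the 24 genes named from the lists, adjusted p (edgeR quasi-likelihood, Benjamini-Hochberg) ran from 2.01e-24 to 0.00926, with the direction in 3 of 3 libraries. Both the call and this direction were required by the naming rule. The resident-macrophage-like class held 69, 73 and 85 cells in replicates 1, 2 and 3, and free RNA could account for at most 18.0%, 19.9% and 32.4% of its UMIs, against 16.3%, 14.9% and 20.4% in infiltrating-monocyte-like cells. With cells thinned to equal depth and number, 281 genes were called, and Cd44 (-0.40) was not. Nos2 turned to 0.66 at resolution 0.5 and to 0.32 at resolution 2.0, and with no replicate block its edgeR adjusted p (Benjamini-Hochberg) was 0.0904. At resolution 0.5, Cxcl2 (-0.82), Cxcl1 (-0.58), Cxcl10 (-0.68), Cd44 (-0.84), Isg15 (-0.91), Ptgs2 (-0.92) and Osm (-0.997) were not called, nor was Cxcl10 at resolution 2.0 (-0.90). Calls ended for C3ar1 without replicate 2 (0.97) and for Saa3 (0.96) and Sfrp2 (0.91) without replicate 3, and with only the 1 infiltrating sub-cluster led by its markers for C3ar1 (0.77), Saa3 (0.78), Sfrp2 (0.92) and Cd44 (-0.997), where Ccl2 was called (-1.25).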

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

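Free RNA subtracted, pooled tenocyte-like or immature-neutrophil-like cells, mixed profiles kept and the infiltrating sub-cluster led by its markers were tested only after the results were seen. Of 326 values of counts, lists and shares under an alternative, 314 stayed within 1.5 times the count or within 1 SD of the share. List counts were summed here over all comparisons and both directions, so changes within a comparison can cancel. In the lining-fibroblast-like comparison, 64 listed genes were called. At resolution 2.0, 60 of them were tested, 6 had the other sign and 14 were no longer called. The genes called ran from 3850 to 6995 over 16 alternatives for fibroblast-like against monocyte/macrophage-like cells (6307 to 6667 without 1 replicate), from 4814 to 7376 over 17 for neutrophil-like cells (6535 to 6851), from 1415 to 3817 over 15 for lining- against sublining-fibroblast-like cells (2700 to 3009) and from 281 to 2527 over 15 for resident-macrophage-like cells (2154 to 2381). With no replicate block the counts were 6343, 6551, 2841 and 2413.

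Cells thinned to equal depth and number gave 3850, 1603 and 281 genes in the fibroblast-like, lining-fibroblast-like and resident-macrophage-like comparisons, against 6377, 2834 and 2429, and 11 instead of 24 eicosanoid and 15 instead of 28 bone and cartilage genes over all comparisons. Fewer UMIs were tested there by construction, and 9847, 5335 and 1118 genes passed the filter. Resolution 2.0 gave 1415 genes in the lining-fibroblast-like comparison, 966 of them shared with the 2834, 958 in the same direction. It also gave 23.2% neutrophil-like (30.5% in the report) and 2.39% tenocyte-like cells (6.05%). Resolution 0.5 gave 1.503% T cell-like (2.31%) and 6.71% tenocyte-like cells, doublets kept gave 20.8% neutrophil-like cells, and free RNA subtracted gave 39 instead of 23 extracellular matrix genes. The cause was not tested.

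Of 2052 values of named genes, 1736 kept direction and call, 42 kept direction and lost the call, 13 gained it and 6 reversed. Genes not called either way made up the other values, 228 with the same sign and 27 with the other. In the neutrophil-like comparison, Mmp3, Mmp13, Il6 and Cxcl1 gained a call with free RNA subtracted from the other class alone, which raises them by construction. At resolution 2.0 in the lining-fibroblast-like comparison, Mmp13 was 0.64 (edgeR, Benjamini-Hochberg adjusted p = 0.145), Nfkb1 0.16 (0.431), Rrm2 -0.033 (0.940) and Tnfsf11 1.31 (0.00942). Nos2 in the resident-macrophage-like comparison was 0.66 (0.251) at resolution 0.5 and 0.32 (0.586) at 2.0. The cause was not tested. No lining-fibroblast-like comparison could be made at resolution 0.5 and no resident-macrophage-like comparison with UMIs split, since a class was not found. Thinning changed depth and cell number together, so their parts in its lower counts were not told apart.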

Other observations

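The genes that describe the sub-clusters in this part, the free RNA and thinning tests of the lining-fibroblast-like balance, and the Il1b tests were chosen after the results were seen. The T cell-like cells fell into sub-clusters with separate profiles. The largest, of 441 cells, held Cd4 at 472 ± 15.5 CPM (SD, n = 3 libraries), the type 1 cytokine gene Ifng at 308 ± 174, Tnf at 242 ± 69.8 and Tnfsf11 at 253 ± 77.0. Il17a differed widely there, with 23.2, 98.8 and 261 CPM in replicates 1, 2 and 3. A sub-cluster of 193 cells held Foxp3, the regulatory T-cell factor, at 293 ± 31.0 CPM and the IL-2 receptor gene Il2ra at 443 ± 103. It also held the proliferation gene Mki67 at 277 ± 25.7 CPM, against 33.5 ± 7.74 in the largest sub-cluster, so its profile is not of regulatory genes alone. Another 113 cells held the cytotoxic co-receptor genes Cd8b1 at 566 ± 118 and Cd8a at 309 ± 78.5. A sub-cluster of 101 cells held Blk at 723 ± 165, Il23r at 419 ± 36.3 and Il17a at 60.9 ± 10.6 CPM, genes found together in IL-17-producing innate-like T cells.

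Neutrophil-like cells included a sub-cluster of 1856 cells with Isg15 at 1741 ± 337 CPM, Cxcl10 at 863 ± 309.9 and Cd274, which encodes the checkpoint ligand PD-L1, at 961 ± 113. It formed 12.8%, 8.36% and 27.6% of the sub-clustered neutrophil group in replicates 1, 2 and 3. Among the phagocytes, 2194 cells held Spp1 at 3379 ± 436 CPM, the arginase gene Arg1 at 2062 ± 769, the lipid-binding gene Fabp5 at 2459 ± 385 and Gpnmb at 282 ± 88.5. The fibroblast-like cells outside the named sub-classes, 1837 in number, held the acute-phase genes Saa3 at 23299.8 ± 3964 and Hp at 9884 ± 1549 CPM. An endothelial-like sub-cluster of 78 cells held the venule genes Selp at 1070.5 ± 213 and Ackr1 at 1267 ± 183 with Glycam1, a gene of lymph-node-type venules, at 1032 ± 186 CPM. Another, of 112 cells, held the arterial gene Gja5 at 147 ± 20.7 and Cxcl12 at 1878 ± 233 CPM.

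Replicate 2 held more immature-neutrophil-like cells (4.28%, against 1.30% and 0.523%) and progenitor-like cells (1.67%, against 0.350% and 0.132%). Markers of B cell precursors, which marrow holds, were 1.07 times as frequent in replicate 2 as in the others (95% interval 0.898 to 1.26), at 2.04 UMIs in 1000000, which argues against carry-over of marrow with its usual B cell precursors. Erythroid markers were 1.90 times (1.89 to 1.91) and plasmacytoid dendritic cell markers 1.17 times as frequent (1.16 to 1.19), plasmacytoid-dendritic-cell-like cells formed 0.388% of replicate 2 against 0.184% and 0.0976%, and marrow poor in B cell precursors stays open. Over all barcodes, before any filter or naming, immature neutrophil markers were 8.39 times as frequent as in the others together (8.33 to 8.45, counting error only), 5.51 times against replicate 1 and 15.4 times against replicate 3, which argues against doublet removal or cluster naming as the source. No biological explanation was tested, since the series has 1 group.

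In lining- against sublining-fibroblast-like cells, 2.85 times as many genes were lower as higher, a ratio that was 4.90 with library totals alone and 1.75 at resolution 2.0. With cells thinned to equal depth and number the ratio was 2.93, which argues against depth or cell number. The share called lower was 6.75 times as high in the longest of 4 groups of genes by span as in the shortest, with Malat1 and Neat1 lower too, so more nuclear or unspliced RNA in the sublining-fibroblast-like cells is a candidate explanation. With free RNA subtracted the ratio was 1.84, which leaves open whether free RNA adds to it. No biological explanation was tested.

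Il1b in fibroblast-like cells may be free RNA from neutrophils: its ratio to S100a8 and S100a9, relative to all cells of the library, was 1.34 (1.20 to 1.47 over the 3 libraries). Ratios above 1 put Il1b over its free RNA limit, which assumes the make-up of the whole library, but endothelial-like (1.43), T cell-like (1.53) and resident-macrophage-like cells (1.35, 1.12 to 1.63) had similar ratios, and that of neutrophil-like cells ran from 0.860 to 1.54. Free RNA richer in Il1b than the library stays open, as does some Il1b of the fibroblast-like cells' own. In infiltrating-monocyte-like cells it was 5.48 (5.36 to 5.68), which argues against free RNA as the only source there. No biological explanation was tested.

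The 6 sums of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each of the 4 comparisons 1 of the 10 splits, the real one, gave as many genes, with 6377, 6596, 2834 and 2429 called by edgeR and at most 0 in the others. The sums are pairs from 3 libraries, and only 4 of the 10 splits, the real one included, part every pair as the real one does, again with at most 0 genes in the others, each of which mixes the classes on both sides.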
